A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

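Total RNA of fission yeast was compared on 2-colour Agilent arrays, with a cdk8 or a cdk11 deletion mutant in one dye and wild type in the other. Per the labels, cultures of 100 ml were grown at 32 °C in rich YES medium to mid-log phase, RNA was taken up in hot acidic phenol and cleaned on a column, and labelled cRNA was made with Agilent's linear amplification kit. There were 2 biological replicates per mutant, each hybridised on 2 arrays with the dyes exchanged, which makes 8 arrays and 4 replicate values. The labels do not say which wild-type extract was on which array. The mutants were compared with wild type on the same array, which leaves out any spread between wild-type cultures that were not hybridised.

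The files used were the deposited scanner output, made with Agilent Feature Extraction 9.5 per the submitters' processing notes. Its signals are deposited as intensity per spot on a linear scale, with mean signal, local background median and Agilent's own processed signal in each colour. The scanner's own ratio of the colours is on a log10 scale per the file headers and was used only to check the colour direction. The deposited series table is on a log2 scale, as found by comparison. Against the scanner's red over green processed signals of bright probes it gave r of 0.971 to 0.988 and slopes of 0.888 to 0.962. Its values are therefore taken as log2 of Cy5 over Cy3, not turned for swapped arrays, with column medians of 0.0035 to 0.0110. How it was normalized is not given in the sources used here, and it served as an alternative only.

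Each array held 45220 spots, of which 3469 (7.67%) were placeholders and 1417 were controls. Of the 40334 probes, 16008 lay inside 5365 genes named by the files and 24326 lay between genes. Gene names came from the files' systematic identifiers and a RefSeq gene table (ASM294v3), with 5209 genes matched by locus tag, 23 by synonym and 133 not matched and named as in the files. That table was used for names, lengths, classes of RNA and the choice of genes near the chromosome ends. Probe positions are given as in the files, which name no build for them. No array held more than 2 saturated spots, and 6 to 38 spots per array carried an outlier mark on the signal.

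Mean signals were corrected for the local background with limma's normexp (offset 50) and normalized within each array by loess with control spots at weight 0. Probes between genes took part in both steps. Control spots and spots marked as outliers were then left out, swapped arrays were turned, and the dye-swapped pair was averaged. Probes were kept where well above background on all arrays of at least 1 kind of RNA, which left 15333 probes, and the mean over a gene's probes (median 3 per gene) gave 5267 genes. All 4 replicate values entered one limma fit with an intercept per mutant, so that both mutants shared one estimate of the spread, with 2 residual degrees of freedom and a prior of 3.19. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05 over all genes tested. The tools were R 4.3.3, limma 3.58.1 and, for reading files, the data.table package of version 1.17.8.

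The background fit was distorted on some arrays. On 5 arrays, 16 spots lay over 20 units below their local background, at most 6 per array, and all 16 carried Agilent's mark for an outlying background. The fitted background mean fell below -20 in 7 of the 16 channels on 4 arrays, down to -830.0, against -6.78 to -0.970 in the others, and lay between -5.09 and 1.91 in all channels once spots with that mark were left out. The result as designed was kept as the main one, and an alternative that leaves out all spots with that mark (3.57% of probe spots, 1057 to 1789 per array) was added after seeing the data.

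Named genes were chosen by a rule fixed before the data were examined. It takes, for each mutant and for the difference, the 10 largest called changes in each direction with the same sign in both replicates, then cdk8 and cdk11, and then up to 4 called members of each list, or the member with the largest value where none was called. Other genes named with background outliers left out in the comparison of the mutants belong to these too. Of 26 lists, also fixed in advance and all entering the adjustment, 25 are reported here. They were the Mediator kinase module with the Cdk11 complex, the Mediator core, transcriptional kinases and RNA polymerase II, flocculation and adhesion, cell wall synthesis, PBF-dependent and MBF-dependent cell cycle genes, core stress response, heat shock, Pap1-dependent response, iron and copper uptake, phosphate response, thiamine, nitrogen starvation, hexose transport, mating, meiosis and sporulation, histones, ribosomal proteins, ribosome biogenesis, proteasome, mitochondrial respiration, Tf2 retrotransposons, subtelomeric genes and strain markers. The mating, meiosis and marker lists also serve to show other cell types or strain differences. Lists were tested by limma's camera with a preset correlation of 0.01, adjusted over the lists within a contrast. No list passed in any contrast when the correlation was estimated from the replicates instead. That version rests on the 2 residual degrees of freedom, so almost no list could pass it. Flocculation in the cdk8 mutant had an estimated correlation of -0.0739, yet its unadjusted camera p went from 1.735e-05 to 0.0454. Failing that version therefore does not show that correlation between genes accounts for a call, and no conclusion is drawn from it.

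A dye effect was tested on the 8 arrays with replicate as a random block, and 1384 of 5266 genes (26.3%) showed one, which averaging the swaps removes from a mean with both orientations. The scripts were tested on simulated data with 200 changed genes per mutant among 5267. The simulated arrays had the same spread for every gene, undistorted backgrounds and no spots marked as outliers. The rates therefore do not show how the scripts performed on the real arrays. In the simulated cdk8 comparison 94% of the 1.25-fold changes and 100% of the 1.5-fold, 2-fold and 4-fold changes were called, with 7.51% wrong calls, and in the simulated cdk11 comparison 96% and 100%, with 4.81% wrong calls. With a steeper dye curve, 12.4% and 13.5% of the calls were wrong, for cdk8 at a median log2 intensity of 16.5 against 9.91 over all genes. A list shifted in the simulation was called, and 0 of 24 random lists were. Members of these lists were simulated with independent noise, so camera was not tested on lists whose members vary together.

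The alternatives were other background corrections, Agilent's processed signals, median centring, quantile scaling between arrays, other probe filters, the series table, other gene summaries, all 8 arrays with a dye term, a single dye orientation, each mutant alone, a replicate block, other prior variances, stricter thresholds and leaving out each replicate. Probes between genes were fitted separately in the same way. A slide block was not run, since the files do not say which arrays shared a slide.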

Results

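Gene expression was measured in fission yeast, Schizosaccharomyces pombe, lacking either cdk8 or cdk11, with wild-type RNA in the other colour of every array. Cdk8 is the kinase of the dissociable kinase module of Mediator, the coactivator complex that works with RNA polymerase II, and Cdk11 is a kinase that works with cyclin L. The series concerns how Cdk11 and its cyclin bear on Mediator assembly, and these arrays ask which transcripts each deletion changes and how far the changes are shared. Each mutant had 2 biological replicates, and each replicate was hybridised on a dye-swapped pair of arrays, so 8 arrays gave n = 2 per mutant. Median probe signals were 116 to 151 in Cy3 and 148 to 187 in Cy5, over median local backgrounds of 41.5 to 49 and 39 to 40.5. Between 93.5% and 97.7% of the probes inside genes lay well above background in any one channel, and 5267 genes were tested. The number of arrays limits the precision. Values are log2 ratios of mutant over wild type, as the mean of 2 replicates ± SD, and adjusted p values come from limma. A few spots with outlying local background distorted the background fit on 4 arrays. Values with background outliers left out, chosen after the data had been seen, are therefore given beside the main counts and for a part of the genes and lists.

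The deleted genes were examined first. Probes of cdk11 (SPBC18H10.15) lie at 1795491 to 1796260 on chromosome 2 and those of cdk8 (SPAC23H4.17c) at 1576941 to 1577660 on chromosome 1, in the files' coordinates, for which the files name no genome build. The cdk11 transcript fell by 3.03 ± 0.68 in the cdk11 mutant (adjusted p = 0.00751, limma, n = 2) and gave 0.05 ± 0.01 in the cdk8 mutant. The cdk8 transcript gave -0.76 ± 0.59 in the cdk8 mutant and did not pass the threshold (adjusted p = 0.0528, limma, n = 2). Its replicates gave -1.17 and -0.34. All 4 arrays gave a negative cdk8 ratio, and the mutant channel was well above background on 1 of them. With background outliers left out, cdk8 gave -1.25 ± 0.10 in its own mutant (adjusted p = 0.000124, limma) and cdk11 gave -3.90 ± 0.07 in its own. With Agilent's processed signals, the deleted gene cdk8 in cdk8 deletion gave -4.74, so the size of its fall depends on the background treatment and none of these values is exact. Which part of each gene was deleted is not stated, so how much of these probe positions remained in the mutants is open. The uracil synthesis gene ura4 (SPCC330.05c), a common selection marker in this yeast, rose in both mutants. Its value was 4.03 ± 1.88 in the cdk8 mutant (adjusted p = 0.0231) and 5.03 ± 1.00 in the cdk11 mutant (adjusted p = 0.0183). Without background outliers ura4 gave 5.39 ± 0.02 and 5.86 ± 0.05.

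**Figure D1:**
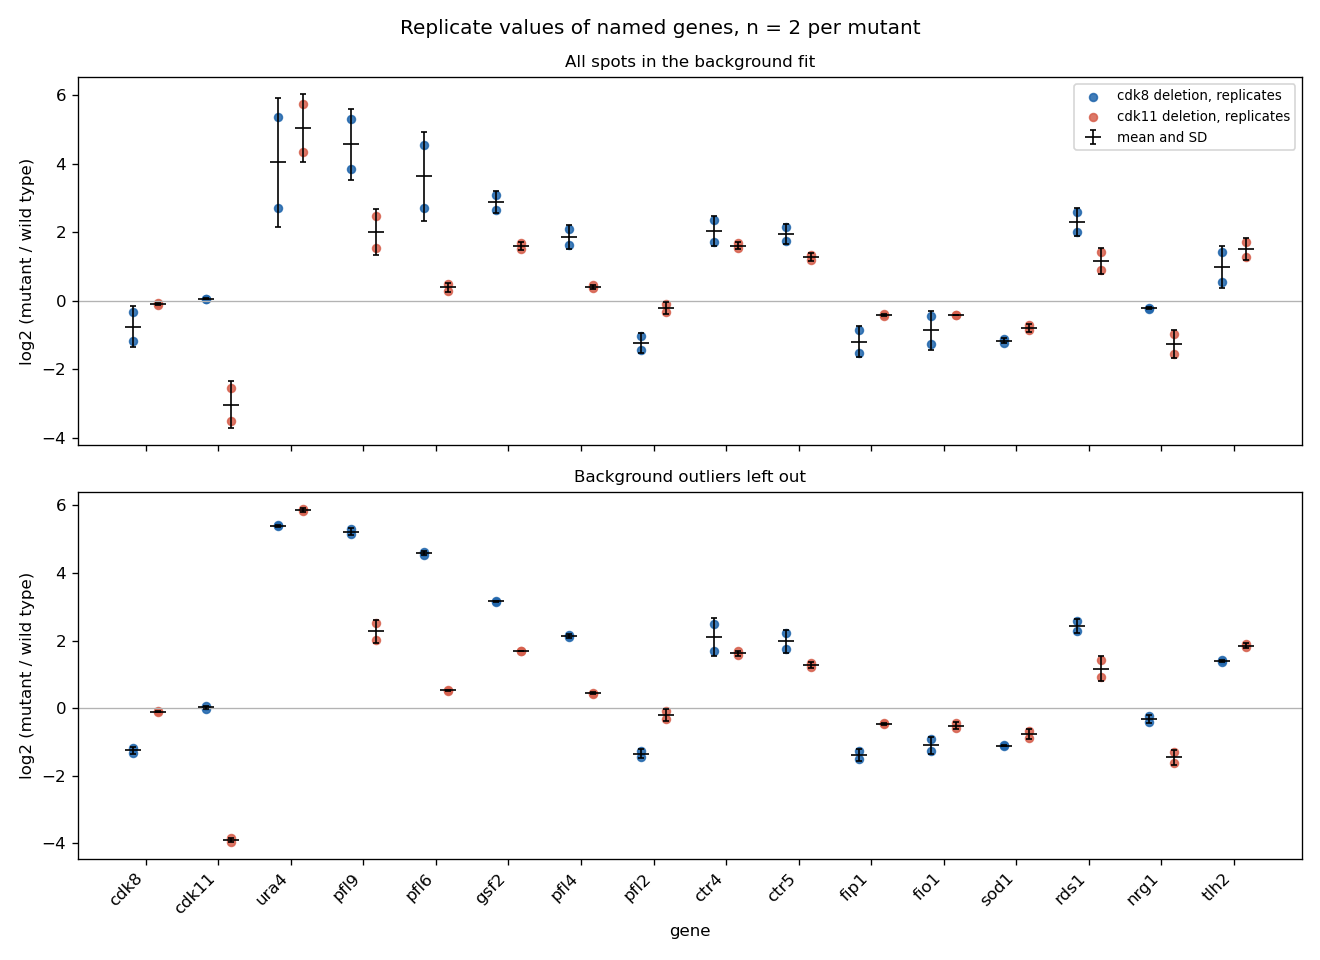
Log2 ratios of mutant over wild type for 16 named genes, with each replicate as a point (blue, cdk8 deletion; red, cdk11 deletion) and the mean and SD as bars, n = 2; the upper panel has all spots in the background fit and the lower panel has background outliers left out. The spread between replicates of ura4 in the cdk8 mutant is 1.88 in the upper panel and 0.02 in the lower, while pfl6 lies far above 0 in the cdk8 mutant and near 0.5 or below in the cdk11 mutant in both panels.

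In cells without cdk8, several genes for cell-surface adhesion proteins were among the largest rises. The flocculin genes pfl9 (4.56 ± 1.03, adjusted p = 0.00559), pfl6 (3.63 ± 1.30, adjusted p = 0.0101), gsf2 (2.87 ± 0.32, adjusted p = 0.00131) and pfl4 (1.85 ± 0.34, adjusted p = 0.00290) rose, all tested by limma. The genes ctr4 (2.04 ± 0.45) and ctr5 (1.94 ± 0.29), which encode the subunits of the high-affinity copper transporter, rose as well, as did rds1 and SPAPB24D3.07c (2.55 ± 0.31). The iron uptake genes fip1 (-1.19 ± 0.46) and fio1 (-0.87 ± 0.58) and the copper-zinc superoxide dismutase gene sod1 (-1.17 ± 0.08) fell, as did the aldehyde dehydrogenase gene atd1 (-1.09) and the flocculin gene pfl2 (-1.24 ± 0.30). In all, 821 of 5267 genes changed at an adjusted p under 0.05, 525 higher and 296 lower, and 18 of the higher and 7 of the lower by at least 2-fold.

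Among the 12 measured flocculation and adhesion genes, 7 rose and 1 fell in the cdk8 mutant, with the same counts adjusted over the list alone and a median of 0.89. limma's camera, which compares a list with all other genes, gave an adjusted p of 0.000113 for this list with a preset correlation, and adjusted p = 0.667 with an estimated correlation. The member that fell was pfl2. Of 48 genes within 50 kb of the ends of chromosomes 1 and 2, 19 rose and 2 fell (32 and 2 adjusted over the list alone), with a median of 0.34 and an adjusted camera p of 6.93e-09 (adjusted p = 0.772 with an estimated correlation). Leaving out background outliers, 34 rose and 2 fell. They include pfl6, the helicase gene tlh2 (0.98 ± 0.60) and the genes ftm4 (0.75 ± 0.12) and ftm1 (0.73 ± 0.12). Many genes near the chromosome ends, including tlh1 and tlh2, the Tf2 elements and duplicated histone and ribosomal protein genes have near-identical copies whose probes cannot be told apart with certainty.

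Of 29 nuclear genes of mitochondrial respiration, 12 rose and 0 fell in the cdk8 mutant (17 and 0 adjusted over the list alone), with a median of 0.15. Among them were qcr7 (0.27 ± 0.08), atp14 (0.24 ± 0.05) and cox6 (0.24 ± 0.08). The adjusted camera p was 5.40e-06 (adjusted p = 0.667 with an estimated correlation). Of 18 heat shock and chaperone genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.08. The list's adjusted camera p was 0.00247 (adjusted p = 0.772 with an estimated correlation). The genes hsp16 (0.74 ± 0.21), psi1 (0.62 ± 0.16), hsp104 (0.56 ± 0.21) and ssa1 (0.38 ± 0.11) rose most. Of 22 genes of the core stress response, 10 rose and 3 fell (10 and 4 adjusted over the list alone). The largest of these changes were rds1 (2.29 ± 0.41) and gpd1 (0.65 ± 0.19) upward and sro1 (-0.64 ± 0.10) and obr1 (-0.52 ± 0.06) downward. The core stress list did not stand apart by limma's camera (adjusted p = 0.178).

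In the cdk8 mutant, 4 lists passed limma's camera in the lower direction, with small values. Ribosome biogenesis had 0 of 54 genes rise and 9 fall (0 and 10 adjusted over the list alone), with a median of -0.07. Its adjusted camera p was 1.855e-05 (adjusted p = 0.667 with an estimated correlation), and dbp9 (-0.25 ± 0.01) and sof1 (-0.24 ± 0.06) fell most. Of 11 histone genes, 0 rose and 5 fell (0 and 7 adjusted over the list alone), with a median of -0.14. The histones' adjusted camera p was 0.00103 (adjusted p = 0.667 with an estimated correlation), and hta1 (-0.26 ± 0.05) and hhf2 (-0.21 ± 0.06) were among them. The histone call was kept with background outliers left out (median -0.13, adjusted p = 0.0251) and lost with processed signals (median -0.11, adjusted p = 0.0696). The list of transcriptional kinases, cyclins and RNA polymerase II subunits had 0 of 21 genes rise and 3 fall (0 and 4 adjusted over the list alone). Its adjusted camera p was 0.0215 (adjusted p = 0.667 with an estimated correlation). The 3 that fell were rpb8 (-0.29 ± 0.02), the Cdk9 cyclin gene pch1 (-0.21 ± 0.05) and rpb6 (-0.20). Median centring in place of loess, run only with all spots in the background fit, moved the median of all genes by 0.24 in the cdk8 mutant. The list medians of ribosome biogenesis (0.26), histones (0.31) and RNA polymerase II genes (0.21) then lay close to that shift, and those 3 calls were lost. All genes named here then lay above 0, as most genes did, and relative to the median of all genes sof1 (-0.169), dbp9 (-0.159), rpb8 (-0.117), pch1 (-0.116), rpb6 (-0.0269) and hta1 (-0.0177) stayed lower and hhf2 (0.0399) did not. Of 141 cytosolic ribosomal protein genes, 0 rose and 8 fell (0 and 2 adjusted over the list alone), with a median of -0.03. Their adjusted camera p was 0.00960 (adjusted p = 0.772 with an estimated correlation). That call was lost with background outliers left out (adjusted p = 0.985). The direction turned upward with Agilent's processed signals (median 0.03, adjusted p = 0.0453) and with median centring (adjusted p = 2.371e-07).

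The other fixed lists did not stand apart in the cdk8 mutant by limma's camera. Iron and copper uptake had 3 of 16 genes rise and 2 fall, and 6 and 2 adjusted over the list alone (adjusted p = 0.359, limma). The Pap1-dependent oxidative and drug response had 2 of 14 rise and 2 fall (3 and 7 adjusted over the list alone, adjusted p = 0.132). Its members sod1 and obr1 fell and the catalase gene ctt1 (0.29 ± 0.13) and gst3 (0.19) rose. Nitrogen starvation and amino acid uptake had 1 of 20 rise and 3 fall (2 and 3 adjusted over the list alone, adjusted p = 0.136), led by isp7 (-0.87 ± 0.36) and the ammonium transporter gene amt1 (-0.54 ± 0.16). Mating type and pheromone response had 3 of 19 rise (3 adjusted over the list alone, adjusted p = 0.498), with rgs1 (0.63 ± 0.23) the largest. Meiosis and sporulation had 2 of 33 rise and 2 fall (2 and 1 adjusted over the list alone, adjusted p = 0.567). Cell wall synthesis had 2 of 25 rise (2 adjusted over the list alone, adjusted p = 0.963), with gas2 (0.66 ± 0.01) the largest. Hexose transport had 2 of 19 rise and 1 fall (2 and 2 adjusted over the list alone, adjusted p = 0.643). The phosphate list had 2 of 8 fall (1 up and 2 down adjusted over the list alone, adjusted p = 0.359). Of the 15 MBF-dependent genes suc22 (-0.21) fell, also adjusted over the list alone (adjusted p = 0.0586). That list passed with background outliers left out, with 5 down (adjusted p = 0.0403, and adjusted p = 0.588 with an estimated correlation). Of the 15 PBF-dependent genes mob1 (0.21 ± 0.07) rose, and 0 did adjusted over the list alone (adjusted p = 0.160). The proteasome had 2 of 33 rise, also adjusted over the list alone (adjusted p = 0.643). No gene passed among 17 Mediator core genes (adjusted p = 0.551) and 6 genes of the Mediator kinase module and Cdk11 complex (adjusted p = 0.519). None passed among 7 thiamine-regulated genes (adjusted p = 0.519) and 3 Tf2 retrotransposons (adjusted p = 0.470) either. The 12 strain marker genes had 2 rise and 4 fall, the same adjusted over the list alone (adjusted p = 0.498). Among them ura4 rose, and ura1 (-0.33 ± 0.16), leu3 (-0.22 ± 0.05) and leu2 (-0.19 ± 0.01) fell. Relative to the median of all genes, which median centring moved by 0.24, ura1 then gave -0.176, leu3 -0.000564, leu2 0.0261 and suc22 0.0134. Leaving out background outliers, the counts adjusted over all genes tested were 6 up and 4 down for iron and copper uptake, 2 and 6 for Pap1, 2 and 7 for nitrogen, 4 and 3 for mating, 5 and 5 for meiosis, 2 and 2 for cell wall, 2 and 2 for hexose transport and 1 and 2 for phosphate. They were 1 and 4 for PBF, 2 and 0 for thiamine, 0 and 1 for the Mediator core and for the kinase module, and as before for the proteasome, Tf2 and strain marker lists.

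With background outliers left out, limma called 1319 genes in the cdk8 mutant, 700 higher and 619 lower, so the higher share was 53.1% in place of 63.9%, and 787 of the 821 genes were called in both. Of the 1319, 31 higher and 14 lower genes changed by at least 2-fold. With all spots in the background fit, the count of 821 was 15 with median centring in place of loess.

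In cells without cdk11, several flocculin genes rose too. The flocculin genes pfl9 (2.00 ± 0.67, adjusted p = 0.0312), gsf2 (1.59 ± 0.12, adjusted p = 0.00732), pfl3 (1.07 ± 0.20, adjusted p = 0.0176) and pfl8 (0.93 ± 0.02, adjusted p = 0.00448) rose, as tested by limma. So did the copper transporter genes ctr4 (1.60 ± 0.10) and ctr5 (1.26 ± 0.11), the stress gene rds1 (1.15 ± 0.38) and tlh2, by a factor of 2.84. Besides cdk11, the largest falls were nrg1 (-1.26 ± 0.42), SPCC663.08c (-0.99 ± 0.36), isp7 (-0.98 ± 0.32), meu3 (-0.96 ± 0.43) and the alcohol dehydrogenase gene adh8 (-0.96 ± 0.25). The superoxide dismutase gene sod1 (-0.79 ± 0.11) fell too. The secreted acid phosphatase gene pho1 (0.78 ± 0.28, adjusted p = 0.0225) and the phosphate transporter gene pho84 (0.40 ± 0.10, adjusted p = 0.0172) rose. In the cdk8 mutant pho1 gave 0.02 ± 0.25 and pho84 gave 0.06 ± 0.07, and neither difference between the mutants passed the test (adjusted p = 0.151 and 0.144, limma). In all, 885 genes changed, 455 higher and 430 lower, and 10 of the higher and 2 of the lower by at least 2-fold.

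Of the 12 flocculation and adhesion genes, 5 rose and 0 fell in the cdk11 mutant (6 and 0 adjusted over the list alone), with a median of 0.39. The adjusted camera p was 0.0207 (adjusted p = 0.867 with an estimated correlation). Ribosome biogenesis had 1 of 54 rise and 13 fall, the same adjusted over the list alone, with a median of -0.06, and nop52 (-0.28 ± 0.07) and dbp2 (-0.25 ± 0.08) fell most. Its adjusted camera p was 0.00617 (adjusted p = 0.867 with an estimated correlation), and median centring ended this call (median -0.05, adjusted p = 0.140). Of 141 ribosomal protein genes, 0 rose and 15 fell (0 and 10 adjusted over the list alone), with a median of -0.04, among them rpl102 (-0.31 ± 0.06) and rpl1603 (-0.26 ± 0.04). Their adjusted camera p was 0.00617 (adjusted p = 0.867 with an estimated correlation). This call was lost with background outliers left out (median -0.05, adjusted p = 0.0635) and with processed signals (median -0.000771, adjusted p = 0.623), and median centring turned the list's median to 0.07. Genes near the chromosome ends had 17 of 48 rise and 5 fall (20 and 8 adjusted over the list alone), with a median of 0.14, and limma's camera gave an adjusted p of 0.09999. That list passed with background outliers left out, with 22 up and 10 down (adjusted p = 0.00548, and adjusted p = 0.780 with an estimated correlation). All 3 Tf2 retrotransposons rose, also adjusted over the list alone, with Tf2-11 at 0.21 ± 0.08, while the list test gave an adjusted p of 0.0681. Their estimated correlation was 0.989, or 0.489 without background outliers, so the 3 are not independent members.

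Further lists in the cdk11 mutant did not pass limma's camera. Heat shock and chaperones had 6 of 18 rise, led by hsp16 (0.50 ± 0.01), and 7 up and 1 down adjusted over the list alone (adjusted p = 0.09999). The core stress response had 6 of 22 rise and 2 fall (7 and 5 adjusted over the list alone, adjusted p = 0.898). The Pap1 list had 1 of 14 rise and 5 fall, the same adjusted over the list alone (adjusted p = 0.0681). In it sod1 and caf5 (-0.60 ± 0.29) fell and gst3 (0.39 ± 0.05) rose. Iron and copper uptake had 3 of 16 rise, namely ctr4, ctr5 and the vacuolar copper transporter gene ctr6 (0.52 ± 0.03), and 3 adjusted over the list alone (adjusted p = 0.357, limma). The phosphate list had 2 of 8 rise and 1 fall, vtc4 (-0.39 ± 0.08), also adjusted over the list alone (adjusted p = 0.759). Nitrogen starvation and amino acid uptake had 3 of 20 fall (5 adjusted over the list alone, adjusted p = 0.198). Mating type and pheromone response had 1 of 19 rise and 2 fall (3 and 6 adjusted over the list alone, adjusted p = 0.142), with the M-factor pheromone gene mfm2 (-0.44 ± 0.09) the largest. Meiosis and sporulation had 1 of 33 rise and 1 fall, the same adjusted over the list alone (adjusted p = 0.689). Mitochondrial respiration had 4 of 29 rise and 2 fall (5 and 2 adjusted over the list alone, adjusted p = 0.142). The RNA polymerase II list had 4 of 21 fall (4 adjusted over the list alone, adjusted p = 0.09999). Histones had 2 of 11 fall (3 adjusted over the list alone, adjusted p = 0.142). The proteasome had 5 of 33 rise (5 adjusted over the list alone, adjusted p = 0.357). In the Mediator core, 2 of 17 genes fell, srb6 (-0.22 ± 0.07) and med20 (-0.17 ± 0.03), with 1 up and 4 down adjusted over the list alone (adjusted p = 0.142). In the Mediator kinase module and Cdk11 complex 1 of 6 fell, cdk11 itself, also adjusted over the list alone (adjusted p = 0.431). Cell wall synthesis had 4 of 25 rise and 1 fall, gas1 (-0.41 ± 0.04), also adjusted over the list alone (adjusted p = 0.143). Hexose transport had 2 of 19 rise and 2 fall (2 and 4 adjusted over the list alone, adjusted p = 0.490). The PBF list had 1 of 15 rise, mob1 (0.35 ± 0.08), also adjusted over the list alone (adjusted p = 0.759). The MBF list had 1 of 15 rise, cdt2 (0.20 ± 0.02), and 0 adjusted over the list alone (adjusted p = 0.404). The thiamine list had 1 of 7 fall, thi4 (-0.16 ± 0.01), also adjusted over the list alone (adjusted p = 0.852). The strain markers had 1 of 12 rise, ura4, and 1 fall, ura1 (-0.31 ± 0.08), also adjusted over the list alone (adjusted p = 0.357). Without background outliers, the counts adjusted over all genes tested were 7 up and 0 down for flocculation, 7 and 6 for core stress, 1 and 6 for Pap1, 4 and 3 for iron and copper uptake, 0 and 6 for nitrogen, 2 and 6 for mating and 2 and 4 for meiosis. They were 3 and 2 for respiration, 0 and 6 for RNA polymerase II, 0 and 1 for histones, 5 and 1 for the proteasome, 0 and 4 for the Mediator core, 3 and 1 for cell wall, 2 and 3 for hexose transport, 2 and 0 for MBF and 0 and 0 for thiamine. The heat shock, phosphate, kinase module, PBF and strain marker lists had the same counts as before.

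Without the background outliers, limma called 1185 genes in the cdk11 mutant, 579 higher and 606 lower, and 814 of the 885 genes were called in both. Of the 1185, 12 higher and 9 lower genes changed by at least 2-fold. With all spots in the background fit, the count of 885 was 2 with median centring in place of loess.

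**Figure D2:**
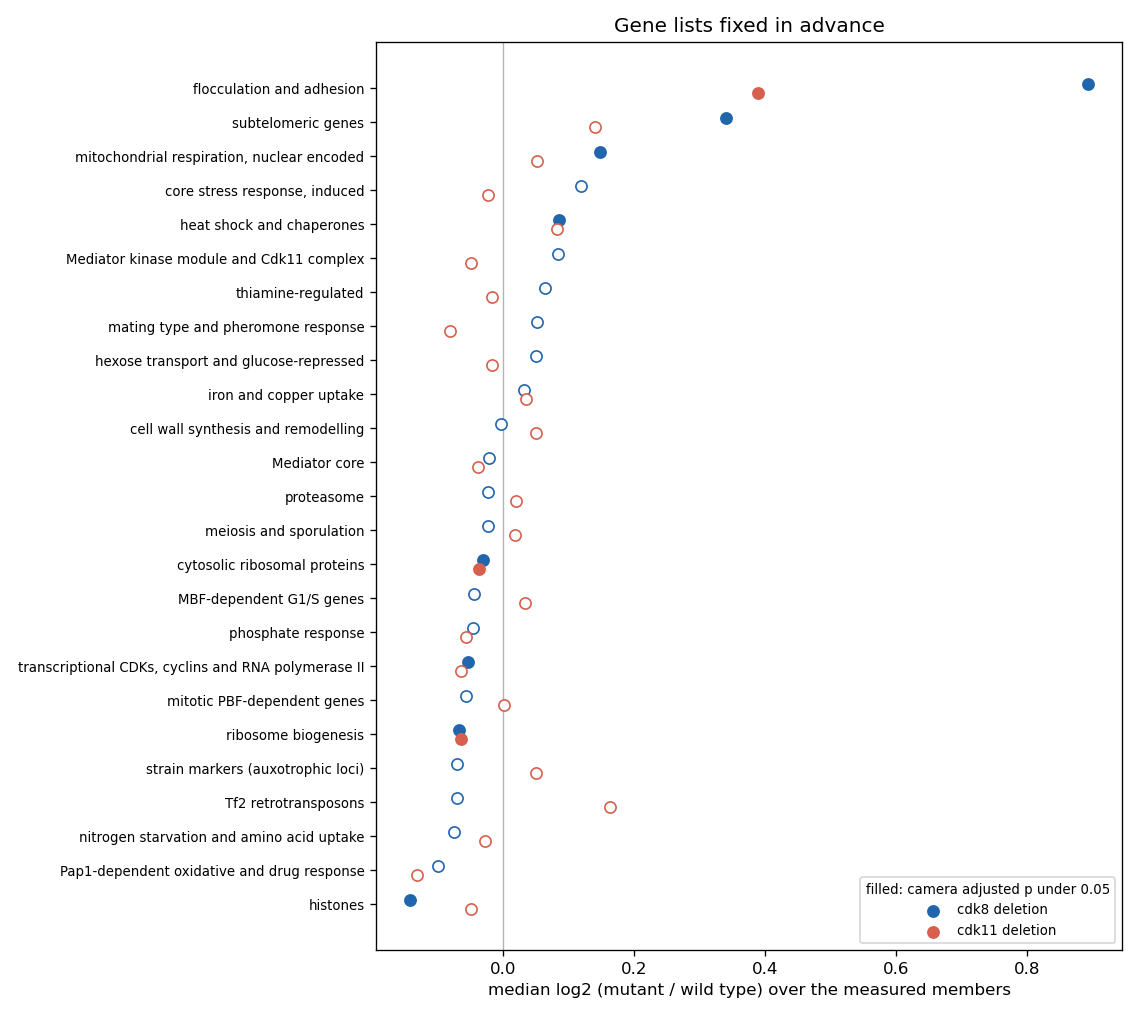
Median log2 ratio of mutant over wild type over the measured members of each of 25 of the 26 gene lists fixed before the data were examined, in the cdk8 mutant (blue) and the cdk11 mutant (red); filled circles passed limma's camera test with a preset correlation and open circles did not. Flocculation and adhesion lies farthest to the right in both mutants, at 0.89 and 0.39.

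The mutants changed many of the same genes in the same direction. Of the genes called in each, 353 were called in both with the same sign, 220 higher and 133 lower, and 10 with opposite signs. The shared genes that rose include pfl9, gsf2, ctr4, ctr5, rds1, SPAPB24D3.07c and hsp16, and the shared genes that fell include sod1, atd1, isp7, SPCC663.08c and pho842. Independent lists of the same sizes would share 45.4 higher and 24.2 lower genes (Fisher's exact test, two-sided, p = 1.46e-113 and 8.36e-72, with genes that are not independent replicates). Log2 ratios of the mutants correlated across all genes tested with r = 0.691 and rho = 0.579, and with r = 0.685 without ura4, cdk8 and cdk11. Unchanged mutants simulated against shared wild-type RNA gave a mean r of 0.494 and a covariance of 0.00125, where the observed covariance, without ura4, cdk8 and cdk11, was 0.0231. At most 1 gene was called in both in the same direction in 100 simulations, a low count that is built in since nothing was changed. Mutant and wild-type RNA had the same simulated spread, which fixes that r in advance. Wild-type values were drawn separately for each replicate number, so a difference common to all wild-type RNA could not appear. Replicates with different numbers, which share no wild-type extract if extracts follow the numbers, gave r of 0.602 and 0.572 over all genes tested. Without ura4, cdk8 and cdk11 these replicates gave r of 0.574 and 0.567 and a covariance of 0.0208. Which wild-type extract was on which array is not stated, so part of the excess may come from shared controls. Leaving out background outliers, 554 genes were shared, 296 higher and 258 lower, where independent lists would share 77.0 and 71.3. With all spots in the background fit, the shared count of 353 was 1 with median centring in place of loess.

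**Figure D3:**
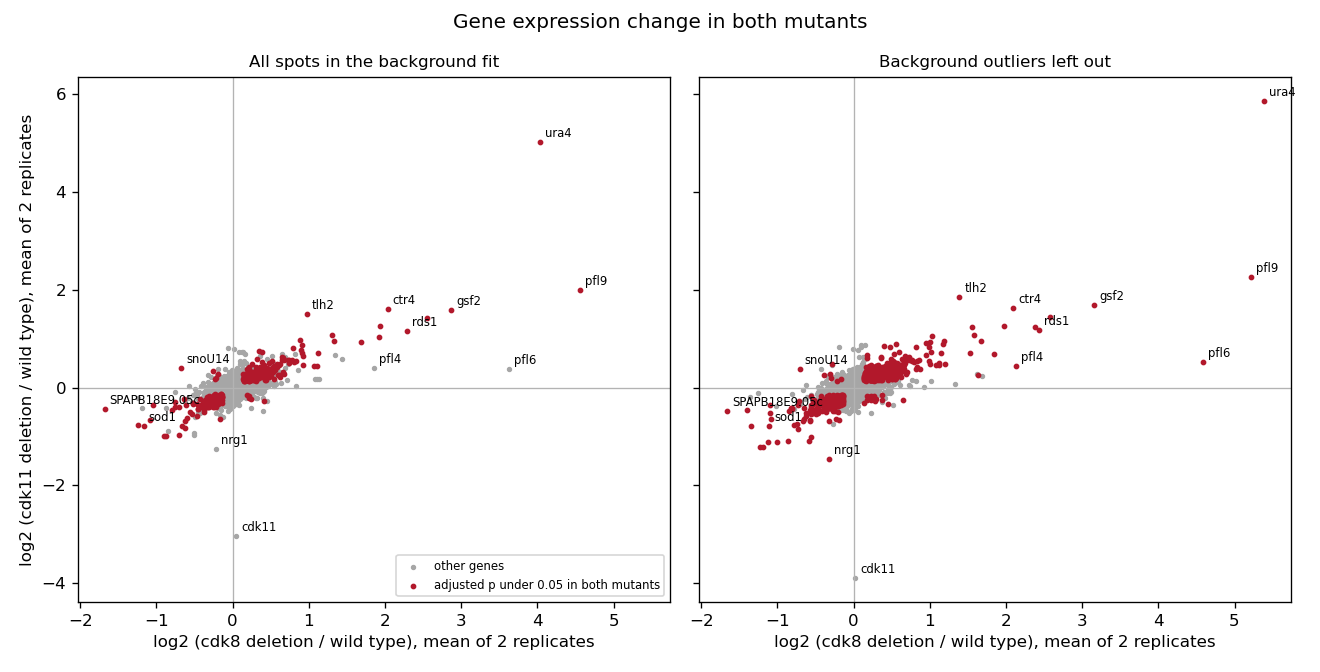
Log2 ratio of mutant over wild type of each gene in the cdk8 mutant (horizontal) against the cdk11 mutant (vertical), as the mean of 2 replicates, with genes called in both mutants in red and all others in grey; the left panel has all spots in the background fit and the right panel has background outliers left out. Genes lie along the rising diagonal (r = 0.691 on the left and 0.681 on the right), pfl6 lies far to the right with a small vertical value, and cdk11 lies at the bottom.

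A direct test of the difference between the mutants, with their replicates not paired, called few genes. Pairing the replicates by number, a pairing that no label states, called 1241 genes instead. The gene SPAPB18E9.05c fell more in the cdk8 mutant (-1.68) than in the cdk11 mutant (-0.44 ± 0.02, difference 1.24, adjusted p = 0.00409, limma). The box C/D small nucleolar RNA genes snoU14 (-0.67 ± 0.06 against 0.40 ± 0.01, difference 1.07, adjusted p = 0.00840) and snoR47 (-0.06 against 0.81 ± 0.05, difference 0.87, adjusted p = 0.0124) were higher in the cdk11 mutant. These were the 3 genes that passed the unpaired test, all higher in the cdk11 mutant, while 933 had an unadjusted p under 0.05. Median centring moved the median difference of all genes from -0.00888 to -0.27. On that shifted scale it called 3 genes, all lower in the cdk11 mutant and 0 of them shared with these, and SPAPB18E9.05c gave 0.85, snoU14 0.71 and snoR47 0.58 (adjusted p = 0.812 each). In the unpaired test with loess, the largest differences among the flocculins, pfl6 (-3.24, adjusted p = 0.134, limma) and pfl9 (-2.56, adjusted p = 0.148), did not pass. That of cdk11 itself (-3.08) did not either (adjusted p = 0.0917).

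With background outliers left out, limma called 115 genes between the mutants, 37 higher and 78 lower in the cdk11 mutant, with the same 3 among them. In that setting the flocculin genes pfl6 (difference -4.05, adjusted p = 5.61e-06), pfl9 (-2.95, adjusted p = 0.00181), pfl4 (-1.69, adjusted p = 0.000281) and gsf2 (-1.47, adjusted p = 0.000308) were higher in the cdk8 mutant, as were rds1 (-1.26) and nrg1 (-1.14), while pfl2 (1.15) and fip1 (0.93) were lower there. Of the 115, 83 had the larger change in the cdk8 mutant and 68 had the same sign in both mutants. The count of 3 was 8 without cdk8 replicate 1, 32 without cdk8 replicate 2, 80 without cdk11 replicate 1 and 93 without cdk11 replicate 2.

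By camera on the difference, 9 of the 26 lists passed, of which 8 are described here, and each gave adjusted p = 0.703 with an estimated correlation. Relative to all other genes, the subtelomeric genes (median difference -0.13, adjusted p = 0.000207), the flocculation genes (-0.16, adjusted p = 0.00357), the mitochondrial respiration genes (-0.12, adjusted p = 0.003105) and the mating genes (-0.06, adjusted p = 0.0143) were lower in the cdk11 mutant than in the cdk8 mutant. The MBF-dependent genes (0.10, adjusted p = 0.003105), the Tf2 elements (0.24, adjusted p = 0.00578), the PBF-dependent genes (0.07, adjusted p = 0.0333) and the histones (0.06, adjusted p = 0.0338) were higher there. The 3 Tf2 elements had an estimated correlation of 0.989, far above the preset 0.01, and are not independent members. No member of these lists passed the test of the difference alone over all genes tested, and adjusted over the list alone 5 subtelomeric, 5 flocculation, 4 respiration and 2 mating genes were lower and 1 flocculation, 1 respiration and 3 Tf2 genes were higher in the cdk11 mutant. Over all genes tested with background outliers left out, 2 subtelomeric and 1 flocculation gene were higher and 13 subtelomeric, 5 flocculation and 2 mating genes were lower in the cdk11 mutant. The strain marker list then passed (adjusted p = 0.0310, and adjusted p = 0.541 with an estimated correlation). The histone call was lost with background outliers left out (median 0.06, adjusted p = 0.289) and with processed signals (median 0.04, adjusted p = 0.294). Median centring kept the calls of the flocculation (adjusted p = 2e-10) and respiration genes (adjusted p = 0.00240) and of none of the other 6 described here.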

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

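The technical tests below were chosen after the results were seen. With all spots in the background fit and replicates not paired, 3 of 5267 genes differed between the mutants by limma, all in the direction of higher values in the cdk11 mutant. With background outliers left out 115 of 5263 did, 37 higher and 78 lower. With median centring, which moved the median difference of all genes to -0.27, 3 others did, all lower on that shifted scale. With all spots SPAPB18E9.05c differed by 1.24, the box C/D snoRNA genes snoU14 and snoR47 by 1.07 and 0.87, each with the same sign in every pairing of replicates. Probes between genes, which enter no gene value but take part in the background fit and the loess curve, also gave calls. Of 12826 such probes kept by the same filter, 1204 passed in the cdk8 mutant (979 higher, 225 lower) and 1620 in the cdk11 mutant (1135 higher, 485 lower), 624 of them in both in the same direction. Without background outliers the counts were 4225 and 3964 of 12675, and 1239 in place of 3 differed between the mutants.

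Because 2 of the 3 genes that differed are snoRNA genes, recovery of short RNAs that differed between the RNA preparations is a candidate explanation. With background outliers left out, the 21 snoRNAs of 75 to 112 nt had a median difference of 0.39 between the mutants and the 6 of 172 to 326 nt one of 0.02, so that the short minus the long was 0.37 (permutation p = 0.0311). The permutation was over genes, not replicates. The short ones include snoU14 (1.09) and snoR47 (1.02), whose calls prompted the test. Among 112 tRNA genes, which are short as well, the median difference was 0.17, yet it grew with length (rho = 0.434), so the test cannot tell this explanation from a change in the cells. A single array or dye orientation as the cause is excluded by the arrays themselves, since on all 4 cdk11 arrays the snoRNA median lay above that of every cdk8 array (lowest 0.154 against highest 0.0184).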

How the results depend on the processing

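The alternatives that leave out background outliers or spots far below their background were added after the data had been seen. All others were fixed before. Median centring was run only with all spots in the background fit, where it moved the median of all genes to 0.24 in the cdk8 mutant and -0.27 in the difference. Agilent's processed signals were also median-centred without loess here, and gave 1299 genes in the cdk8 mutant, 1081 in the cdk11 mutant and 518 in both. The count in the cdk8 mutant (821) was 1474 without background correction, 1299 with processed signals, 15 with median centring, 1475 with the series table, 1450 on 8 arrays with a dye term, 1579 with the mutant in Cy3 only, 154 in Cy5 only, 1319 without background outliers, 1435 without spots far below background, 117 at an adjusted p under 0.01 and 25 at 2-fold or more. Without a replicate it was 124 to 1013, with the lone replicate taken to vary like the other mutant's. The count in the cdk11 mutant (885) was 2 with median centring, 1482 on 8 arrays, 271 in Cy5 only, 21 at 0.01, 12 at 2-fold and 322 to 963 without a replicate. Quantile scaling of the average intensities leaves log2 ratios as they are by construction and tests nothing here; robust and trended priors gave 826 and 830 in the cdk8 mutant and 887 and 922 in the cdk11 mutant. Leaving out only the 16 spots far below their background raised the counts to 1435 in the cdk8 mutant and 1279 in the cdk11 mutant. It raised those between and in both mutants to 123 and 614. Those few spots therefore lowered the counts obtained with all spots in the background fit. What caused the other changes in these counts, and in those between and in both mutants, was not tested. Stricter thresholds call fewer genes by construction.

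The count between the mutants (3) was 140 without background correction, 105 with processed signals, 5 with the strict probe filter, 136 with the series table, 7 with the median of probes, 11 with the brightest probe, 207 on 8 arrays, 242 in Cy3 only, 2 in Cy5 only, 115 without background outliers, 123 without spots far below background and 8 to 93 without a replicate. With a replicate block, which pairs replicates by number, it was 1241, and 1317 without background outliers. The counts in the cdk8 mutant, the cdk11 mutant and both were then 2558, 2652 and 1452, or 2773, 2636 and 1500 without background outliers. Against wild type, the block takes the deviation shared by same-numbered replicates out of the error. The p values behind those counts therefore leave out part of the spread between replicates. No label ties the pairs, but deviations of same-numbered replicates from their means correlated between the mutants (r = 0.632), so how far the unpaired count is too low is open. A slide block was not run, since the files give no slide identity. The count in both mutants (353) was 627 without background correction, 1 with median centring, 628 with the series table, 655 on 8 arrays, 651 in Cy3 only, 87 in Cy5 only, 554 and 614 without the outlying and the far-below spots, 14 at 0.01, 9 at 2-fold and 101 to 263 without a replicate; single replicates leave no residual for such a count. The correlation (0.691) was 0.575 with median centring, 0.602 and 0.572 for replicates of different numbers, and 0.636 to 0.680 without a replicate. Of the list calls (8, 3 and 9), 0 passed with an estimated correlation, a version on 2 residual degrees of freedom that almost no list could pass. By fry with all spots, 1, 0 and 1 lists passed: flocculation in the cdk8 mutant, which was among the 8, and strain markers in the difference, which were not among the 9. Without background outliers more lists passed fry, among them flocculation (adjusted p = 0.00261), Pap1 (0.00121) and ribosome biogenesis (0.0107) in the cdk8 mutant. In the cdk11 mutant these 3 lists gave 0.0138, 0.00147 and 0.0144, and flocculation gave 0.0160 in the difference. The core stress list passed fry in neither mutant (0.219 and 0.778). With median centring 7 lists passed in the cdk8 mutant, among them meiosis downward (adjusted p = 5.358e-10) and the proteasome upward (adjusted p = 0.0185), which were not among the 8; 7 passed in the cdk11 mutant, of the 3 only flocculation, and 5 in the difference, of the 9 only flocculation and respiration. The genes with a dye effect (1384) were 2121 without background outliers.

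The deleted gene cdk8 in cdk8 deletion (-0.76) passed with -1.39 without background correction, -4.74 with processed signals, -1.40 with the series table, -1.09 with the brightest probe, -0.76 on 8 arrays and also fitted alone, -0.90 in Cy3 only, and -1.25 and -1.24 without the outlying and the far-below spots; without its replicate 2 it was -1.17 and passed, and without replicate 1 it was -0.34 and did not. Without either cdk11 replicate it passed at -0.76. The deleted gene cdk11 in cdk11 deletion (-3.03) was -2.41 in Cy5 only and did not pass (adjusted p = 0.0506, limma), and -3.51 and -2.56 without a replicate. The cause was not tested. Of 192 named values 161 passed; of these, 154 also did without background outliers, 146 with processed signals, 59 in Cy5 only, 11 with median centring, and 109 to 132 without a replicate. Values of 23 genes in the cdk8 mutant reversed with median centring: rpb8 0.12, pch1 0.12, rpb6 0.21, suc22 0.25, vtc4 0.0278, vtc2 0.20, ptr2 0.12, adh1 0.28, hta1 0.22, hhf2 0.28, htb1 0.27, hta2 0.31, rps3001 0.0664, rps2401 0.12, rps2502 0.22, rpl3202 0.26, dbp9 0.0806, sof1 0.0710, rpf2 0.22, nog2 0.21, ura1 0.0638, leu3 0.24 and leu2 0.27. Median centring moved the median of all genes there by 0.24, and relative to it 16 of the 23 kept their sign. No array was short of signal over background, with 93.5% or more of gene probes well above it in each channel. Of the deleted genes, cdk8 was the dimmer, with its mutant channel well above background on 1 of 4 arrays.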

Other observations

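Classes of RNA other than messenger RNA, grouped by the reference annotation after the data had been seen, gave the following values. Of 112 tRNA genes 30 rose and 0 fell in the cdk11 mutant, and 0 rose and 1 fell in the cdk8 mutant, with medians of 0.13 and 0.05, and the test of the difference between the mutants called 0 of them. With background outliers left out, 42 tRNA genes rose and 2 fell in the cdk11 mutant, 7 rose and 7 fell in the cdk8 mutant, and in the difference 6 were higher and 1 was lower. Of 27 snoRNA genes 13 rose and 4 fell in the cdk11 mutant (median 0.23), 0 rose and 5 fell in the cdk8 mutant (median -0.05), and 2 differed between the mutants by limma, or 7 with background outliers left out. Of 23 rRNA genes 10 rose in the cdk8 mutant (median 0.41) and 3 in the cdk11 mutant (median 0.26), or 21 and 14 with background outliers left out. Labelling of RNAs without a poly(A) tail was not tested here.

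The technical tests that follow were chosen after the results were seen. Log2 ratios of 1756 dim genes spread less in replicate 2 than in replicate 1, with a ratio of SDs of 0.471 for the cdk8 mutant and 0.649 for the cdk11 mutant. A few spots with outlying local background that distort the background fit are a likely cause, since the ratio for the cdk8 mutant was 1.03 once the spots far below their background were left out. A difference of the cultures or RNA of replicate 2 is excluded as the cause by Agilent's processed signals of the same arrays, which gave 0.985 for the cdk8 mutant.

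That the mutants changed the same genes in the same direction could come from wild-type RNA that they share. Wild-type extracts that follow the replicate numbers are excluded as the whole cause, since with background outliers left out the covariance of different-numbered replicates (0.0287) was 87.0% of that of same-numbered ones (0.0329). A difference of the wild-type strain or cultures from both mutants may still contribute. The large rise of ura4 in both mutants is what a wild-type strain without that gene, or with less of it, would give. Without ura4, cdk8, cdk11 and the 100 genes that changed most, r was 0.556, which does not separate this from a shared effect of the deletions.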
